A study of Homo sapiens with 9 samples.

How the data were processed

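The series measured poly(A) RNA of HaCaT cells by sequencing in 9 libraries, 3 each of cells with an empty vector (Vector), with FTO and with a mutant FTO (mut-FTO). Groups and replicate numbers were taken from the sample labels. The deposited table holds whole-number counts per gene, not normalized, which the authors made with HISAT2 and StringTie, per the submitters' processing notes. Versions, the counting program, its strand setting and the annotation are not given in the sources used here. The notes name mm10, a mouse build, although the cells are human and the symbols in the table are human, so no coordinates are printed. The table has 21170 features, of which 1441 are assembled loci with an MSTRG identifier in place of a gene name, and 0 that name no feature at all. Its columns carry short letter codes and were matched to the groups by those letters: the columns without the letter F to Vector, with it to FTO, and with a letter before it to mut-FTO. Counts of the FTO gene had been seen before this match was written down. They tell Vector from the other groups, but the match of FTO and mut-FTO rests on the letters alone. All columns of values were used. Any 2 libraries differed by more than sampling noise, so none was treated as a repeat of another.

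Depth ranged from 32222203 to 37846027 counts per library. Where all 3 libraries of a group had no count of a gene, the group was set at 3 counts in total and a fold is given as a bound. Such bounds use total counts over total library sizes, without the scaling factors named below. Intervals on shares of counts are Wilson intervals at 95%, and intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

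The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group with its minimum count of 10 and minimum total of 15, which left 13713, and libraries were scaled by TMM factors. All 9 libraries entered one model with a term per group, so the 3 groups shared the estimate of the spread. Robust quasi-likelihood fits and tests gave a p per gene and comparison, adjusted by the Benjamini-Hochberg method over the genes tested, and genes below 0.05 were called changed. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM used a prior count of 2. Comparisons were FTO against Vector, mut-FTO against Vector and FTO against mut-FTO.

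Lists of genes were fixed before the data were examined: 28 lists of 821 symbols, of which 763 matched the table by symbol, 57 by an older symbol and 1 not at all. FTO itself was left out of them. Lists with at least 5 tested members (26) were tested with camera of limma 3.58.1 on voom values, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were alternatives. Members without a count in a group entered the median also at their bound, which left every list's median as it was. The marker lists of fibroblasts, leukocytes, melanocytes and endothelial cells stand for cells that could be mixed in.

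Genes are named by a rule fixed before the data were examined. It takes FTO and FN1, then the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between the libraries of the groups. Unnamed identifiers, antisense and read-through names were left out. For lists it takes the 2 to 4 members of lowest p, and for overlaps the 5 genes per direction with the largest smaller change of both comparisons. Families of near-identical genes (SPRR2, KRT6, IFIT, histones) and overlapping or antisense genes are uncertain, since the way reads were assigned to them is not known. Some genes that the rule takes are not reported here.

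Overlaps of calls were compared with the number expected of independent lists and with 20 simulations of unchanged groups that share libraries. The covariance of edgeR fold changes was compared with its simulated value. It was recomputed on log2 CPM with FTO and mut-FTO set against different Vector libraries, with a jackknife over these.

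Alternatives fixed beforehand were RLE size factors, library size alone, FTO left out of library sizes, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 10 counts, only the 6 samples compared, the replicate number as a block, a log2 fold change of at least 1, and each replicate left out. Chosen after the data were seen were the fit without the libraries richest in 4 assembled loci (Vector replicate 3 and mut-FTO replicate 2), the fit without assembled loci and mitochondrially encoded genes, leaving out libraries of the group not compared, the estimated correlation with each library left out, and some settings for the overlaps. Transcript length and GC content came from the longest GENCODE transcript of each gene symbol for 12749 of 13713 tested genes (93.0%). Older symbols were added to that match after the first attempt had covered too few oxidative phosphorylation genes, that is fewer than 80%. A trend in length and GC was removed with a smooth fit, and intervals came from 2000 bootstrap draws of the genes of a list.

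The analysis was tested on simulated counts of the 13713 genes with 200 changed genes, in 3 runs, though the first fits of the real counts came before that test. In FTO against Vector edgeR recovered 82.8% of 4-fold, 40.8% of 2-fold and 0% of 1.5-fold changes, and 5.38% of its calls were false. In mut-FTO against Vector it recovered 83.3%, 37.3% and 3.48%, with 3.52% false, and in FTO against mut-FTO 84.3%, 42.3% and 5.97%, with 8.33% false. DESeq2, in 1 run, made 21.1%, 21.1% and 19.1% false calls. A list moved on purpose was found in 3 of 3 runs per comparison, and no other of the 78 list tests per comparison passed. Simulated genes were independent of each other, so these runs cannot show false list calls that come from correlation between genes. Of shared 4-fold changes planted in FTO and mut-FTO against Vector, 84.8% were recovered in the overlap, and smaller shared changes were not planted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.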

Results

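Poly(A) RNA was sequenced from HaCaT cells, a spontaneously immortalized line of human keratinocytes, the cells that build the epidermis. The 9 libraries formed 3 groups of 3: cells carrying an empty vector (Vector), cells made to express FTO (FTO), and cells made to express a mutant FTO with disrupted demethylase activity (mut-FTO). FTO is an enzyme that removes methyl groups from adenosines in RNA, and the series concerns FTO, psoriasis-like dermatitis and the matrix protein fibronectin, encoded by FN1. Libraries held 33824317, 34005571 and 34999460 counts in Vector, 37846027, 36970745 and 34920540 in FTO, and 36387283, 32222203 and 34876033 in mut-FTO. Of 21170 features in the table, 17167 had at least 1 count and 13713 had enough counts to be tested. Values below are in CPM, that is counts scaled to the normalized library size, given as mean ± SD of 3 libraries, with log2 fold changes and their standard errors (SE). Nothing in the labels states that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Whether a group was a single population of cells is not stated either. The construct of a group therefore cannot be told apart from other traits of its cells.

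The 3 groups separated along the first principal component of the 500 most variable genes, which held 38.7% of their variance. Vector libraries scored −23.53 to −26.06 on it, FTO libraries −3.11 to −5.50 and mut-FTO libraries 26.7 to 32.4, so that FTO lay between the other groups. Vector libraries differed more among themselves than the others did: the median standard deviation of a gene's log2 CPM was 0.37 in Vector, 0.14 in FTO and 0.23 in mut-FTO. Vector replicate 3 stood apart. Mitochondrially encoded genes, which specify subunits of the respiratory chain, took 14.97% of its counts (Wilson 95% interval 14.96 to 14.98). They took 4.16% (4.155 to 4.168) and 4.20% (4.196 to 4.21) in the other Vector libraries, 3.81% to 4.32% in FTO, and 5.52%, 7.45% and 5.77% in mut-FTO, with a widest half-width of 0.0118 points for all 9 shares. Loci assembled without a gene name took 2.498% (2.493 to 2.503) of the counts in Vector replicate 3 and 3.17% (3.163 to 3.175) in mut-FTO replicate 2. In the remaining 7 libraries these loci took 0.689% to 0.875%, and half-widths were at most 0.00605 points in all 9. Such intervals cover counting error alone.

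**Figure D1:**
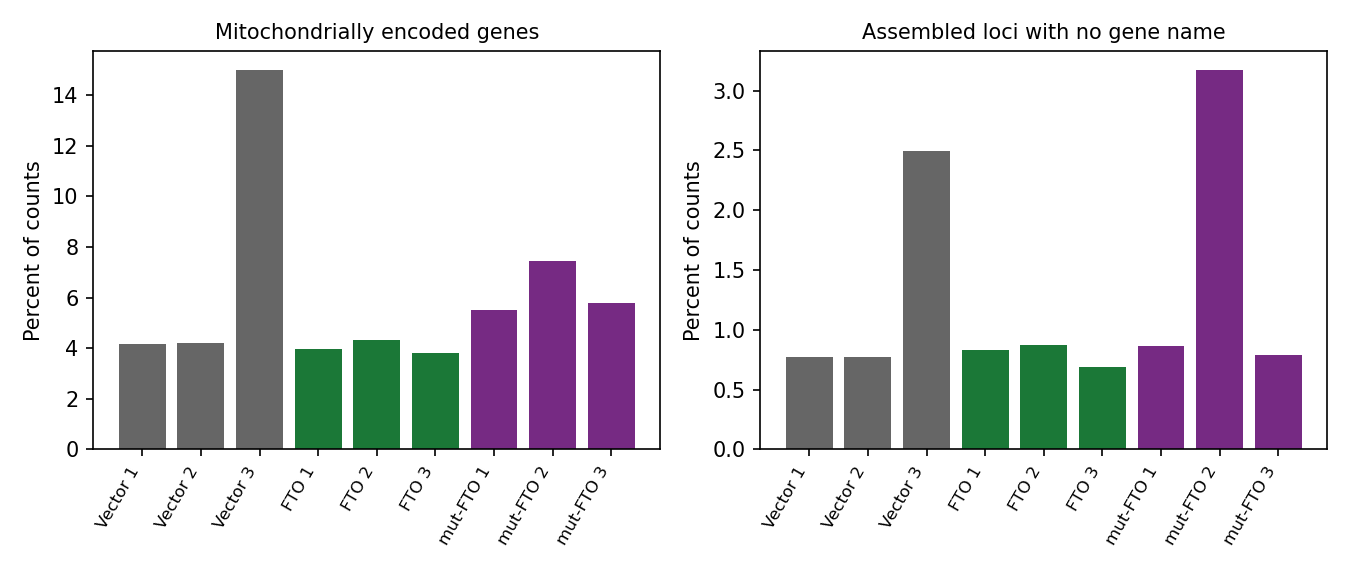
Bars show the percent of all counts in mitochondrially encoded genes and in assembled loci without a gene name (y axes, from 0) for each of the 9 libraries (x axis). Vector replicate 3 reached 14.97% mitochondrial counts, and assembled loci were highest in mut-FTO replicate 2 (3.17%) and Vector replicate 3 (2.498%).

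FTO RNA was raised in both groups made to express the gene, and FN1, which encodes fibronectin, a glycoprotein of the extracellular matrix, fell in both. FTO stood at 20.4 ± 4.75 CPM in Vector, 69.8 ± 7.22 in FTO and 65.5 ± 16.5 in mut-FTO (SD, n = 3 each). Its log2 fold change against Vector was 1.77 in FTO (SE 0.22; adjusted p = 0.00266, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and 1.68 in mut-FTO (SE 0.22; adjusted p = 0.000512). Per library, FTO reached 69.6, 77.1 and 62.6 CPM in the FTO group and 49.7, 82.7 and 64.3 CPM in mut-FTO. Between these groups it differed by 0.091 (SE 0.21; adjusted p = 0.909, same edgeR test), less than the spread between libraries, and by −0.073 without mut-FTO replicate 1 (adjusted p = 0.906). FN1 fell from 243 ± 31.3 CPM in Vector to 30.4 ± 7.58 in FTO and 7.73 ± 1.05 in mut-FTO. This was a log2 change of −3 in FTO (SE 0.21; adjusted p = 5.57e-05) and −4.98 in mut-FTO (SE 0.23; adjusted p = 2.9e-07) by the edgeR quasi-likelihood test. FN1 was also 3.93-fold higher in FTO than in mut-FTO (log2 1.98, SE 0.20; adjusted p = 0.000531, same edgeR test). FTO counts do not separate the cells' own transcript from the introduced one. The FTO level told Vector from the expressing groups but not FTO from mut-FTO, whose columns were told apart by their letters alone. If these were exchanged, the changes of each group against Vector would belong to the other.

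**Figure D2:**
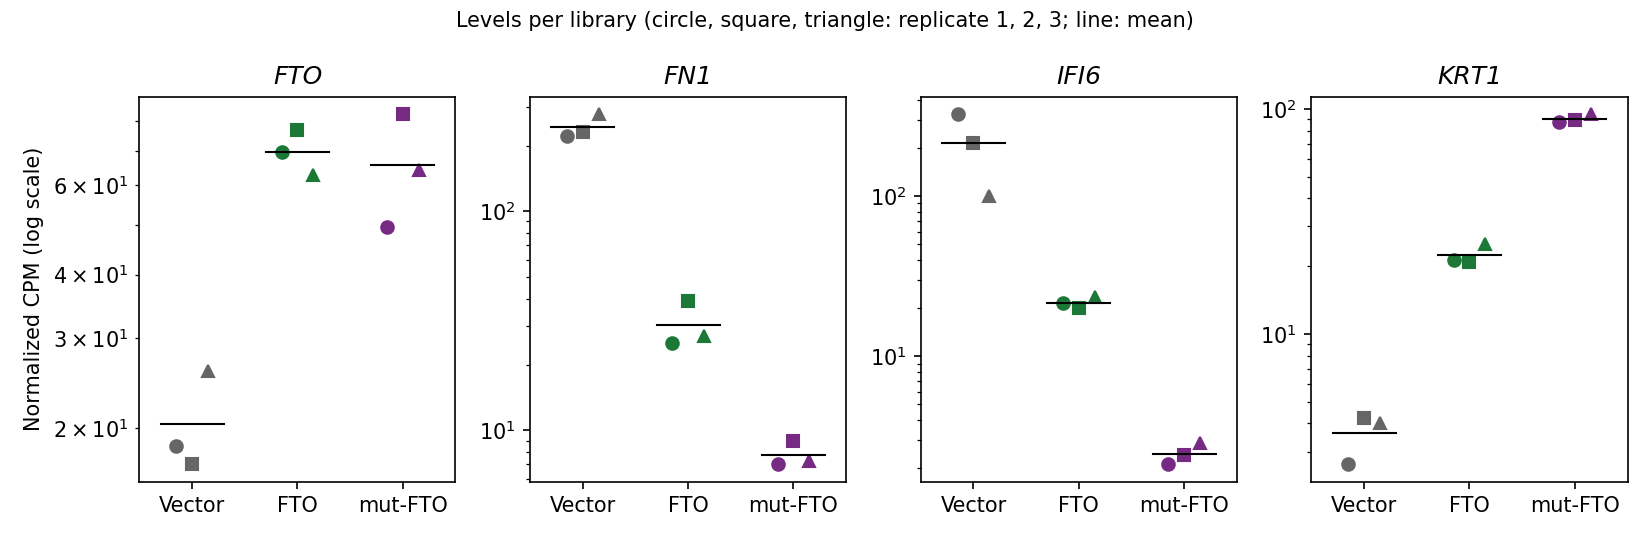
Normalized CPM per library (y axes, log scale) of FTO, FN1, IFI6 and KRT1 in the Vector, FTO and mut-FTO groups (x axis), with circles, squares and triangles for replicates 1, 2 and 3 and a line at each group mean. FN1 and IFI6 were lower and KRT1 higher in FTO than in Vector and in mut-FTO than in FTO, while FTO averaged 69.8 CPM in FTO and 65.5 CPM in mut-FTO.

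Interferon-response genes were lower in FTO than in Vector. Matrix genes fell and keratinocyte differentiation genes rose as lists at a preset correlation between genes, calls that were lost with an estimated one (adjusted p = 0.166 and 0.124). IFI6, an interferon-induced gene, fell 9.92-fold from 214 ± 113 to 21.6 ± 1.68 CPM, and BST2 (tetherin), which holds budding viruses on the cell surface, fell 10.3-fold. KRT1, the keratin of suprabasal keratinocytes, rose 6.16-fold from 3.63 ± 0.870 to 22.4 ± 2.34 CPM. RNASE2, a secreted ribonuclease of eosinophil granules, was not counted in any Vector library and reached 10.1 ± 1.23 CPM in FTO, at least 346-fold higher when the 3 Vector libraries together are set at 3 counts. FABP4, a fatty acid carrier, rose 4.78-fold to 72.0 ± 15.7 CPM, and the glypican GPC4 (7.20-fold), the serine protease TMPRSS11E (4.60-fold) and CCDC69 (4.53-fold) rose as well. These 8 changes, FN1 and FTO passed edgeR's threshold with any of the 9 libraries left out. LSP1, a leukocyte actin-binding protein, rose 40.5-fold and the tight junction gene CLDN8 5.98-fold. The fold of LSP1 rests on 5 Vector counts, all in replicate 1. SERPINA3-1, a second entry of the antichymotrypsin gene SERPINA3 whose reads can be split between the entries, fell 13.1-fold. The interferon-induced IFI27 fell 11.9-fold, the myosin MYO1G 8.31-fold, the gelatinase MMP9 6.81-fold and the transcription factor NFATC1 5.53-fold. IFI27 varied widely in Vector, at 119.2, 87.05 and 17.03 CPM in replicates 1, 2 and 3, against 6.25 ± 0.657 CPM in FTO. Total counts in FTO were 18 for MYO1G, 45 for MMP9 and 37 for NFATC1.

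In total 42 genes rose and 60 fell of 13713 tested at an adjusted p below 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 1631 had an unadjusted p below 0.05. All 102 separated every FTO library from every Vector library, as did 21.0% of all tested genes, where chance gives 10%. DESeq2 called 366 genes, a fit of the 6 samples compared 41, and the fit without Vector replicate 3 and mut-FTO replicate 2 called 1050. Leaving out 1 library gave 476 genes without Vector replicate 3, 50 without Vector replicate 2, 32, 32 and 27 without FTO replicates 1, 2 and 3, and 59 without mut-FTO replicate 3. Among the genes named above, LSP1 and IFI27 lost their call without any FTO library (edgeR adjusted p = 0.0560 to 0.0722 and 0.0722 to 0.0884). CLDN8 lost it without Vector replicate 2 or FTO replicate 3 (0.0518 to 0.0780) and MMP9 without FTO replicate 3 (0.0539). SERPINA3-1 lost it without any FTO library or Vector replicate 2 or 3 (0.0722 to 0.123). MYO1G kept its call only without Vector replicate 3 (0.0615 to 0.186 in the others), and NFATC1 only without Vector replicate 1 or 3 (0.0526 to 0.279).

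Among the gene lists fixed beforehand, the interferon response fell in FTO: 6 of 42 tested members fell, 36 did not pass, and none rose (15 fell adjusted over the list alone). With edgeR, no member had an unadjusted p below 0.05 in the upward direction, and neither DESeq2 nor limma-voom called a rise. MX1 and OAS2, antiviral effectors induced by interferon, fell 4.24-fold to 3.32 ± 0.270 CPM and 3.38-fold to 7.23 ± 0.525 CPM, each with any of the 9 libraries left out. The list's median log2 fold change was −0.52 (camera adjusted p = 3.69e-14; adjusted p = 0.00216 with an estimated correlation). Keratinocyte differentiation genes rose as a list, with a median of 0.56 (camera adjusted p = 1.67e-05; adjusted p = 0.124 with an estimated correlation). Of its 34 tested members 4 rose and 30 did not pass (7 rose adjusted over the list alone), namely KRT1 and the small proline-rich cornified envelope genes SPRR2E (3.32-fold), SPRR2D (2.29-fold) and SPRR2A (1.91-fold). SPRR2 genes are near-identical copies whose reads can be split between them. Without Vector replicate 3 the median was 0.35 and 10 members rose. SPRR2D lost its call without FTO replicate 2 (edgeR adjusted p = 0.0535), and SPRR2A lost it without 7 of the 9 libraries, all but Vector replicates 1 and 3 (0.0603 to 0.228).

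Extracellular matrix genes fell as a list (median −0.39; camera adjusted p = 3.32e-08; adjusted p = 0.166 with an estimated correlation). Of 45 tested members 5 fell, among them FN1, MMP9 and the fibrillar collagen gene COL5A1 (2.91-fold), 2 rose and 38 did not pass (17 fell and 4 rose adjusted over the list alone). COL5A1 lost its call without FTO replicate 1 or 3 (edgeR adjusted p = 0.0722 to 0.0730). Inflammatory cytokine genes fell as a list (median −0.23; camera adjusted p = 0.0133, and 0.0661 without Vector replicate 1; adjusted p = 0.166 with an estimated correlation). IL24, a cytokine of the IL-10 family, fell 2.49-fold to 19.1 ± 2.33 CPM and IL1B, encoding interleukin 1 beta, fell 1.89-fold to 216 ± 23.0 CPM. CXCL8, the neutrophil chemokine interleukin 8, rose 2.11-fold to 507 ± 22.8 CPM. The remaining 25 of 28 did not pass (7 fell and 2 rose adjusted over the list alone). Calls were lost without FTO replicate 1 or 2 for IL24 (edgeR adjusted p = 0.0729 to 0.0884), without any FTO library for IL1B (0.0583 to 0.147), and without 6 libraries for CXCL8, namely all FTO libraries, Vector replicates 1 and 2 and mut-FTO replicate 3 (0.0871 to 0.228). The list of leukocyte markers fell (median −1.27; camera adjusted p = 0.00144; adjusted p = 0.166 with an estimated correlation). Only 7 of its 17 genes were expressed enough to test. Of these LCP1 (plastin 2), an actin-bundling protein, fell 2.41-fold to 26.5 ± 1.89 CPM, CD74, the invariant chain of MHC class II, 4.16-fold and HLA-DRA, an MHC class II chain, 2.61-fold. The other 4 did not pass (the same count of 3 fell adjusted over the list alone). HLA-DRA lost its call without Vector replicate 2 or any FTO library (edgeR adjusted p = 0.0591 to 0.138).

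Ribosomal protein genes had a median log2 fold change of 0.59 in FTO against Vector (camera adjusted p = 1.64e-27; adjusted p = 0.203 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of 0.42 (camera adjusted p = 1.31e-12; adjusted p = 0.316 with an estimated correlation). No single member of either list passed edgeR's threshold over all genes, against 51 of 75 and 12 of 49 at an unadjusted p below 0.05, 7 and 1 by DESeq2, none by limma-voom, and 23 and 1 adjusted over the list alone. Both medians moved with Vector replicate 3, without which they were 0.37 and 0.17 and 7 and 2 members rose. The oxidative phosphorylation median was 0.66 without Vector replicate 1. Mitochondrially encoded genes had a median of −0.95 (camera adjusted p = 0.000198; adjusted p = 0.424 with an estimated correlation), which became −0.054 without Vector replicate 3 (camera adjusted p = 0.841). None of their 13 members passed by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, against 8 at an unadjusted p below 0.05. Glycolysis and hypoxia genes rose as a list (median 0.27, and 0.15 without Vector replicate 3; camera adjusted p = 1.68e-05; adjusted p = 0.2995 with an estimated correlation). MXI1, a MYC antagonist, rose 1.88-fold, the other 34 members did not pass (4 rose and 2 fell adjusted over the list alone), and MXI1 kept its call only without Vector replicate 3 (edgeR adjusted p = 0.0520 to 0.204 in the others). Integrin and focal adhesion genes fell as a list (median −0.20; camera adjusted p = 0.0148; adjusted p = 0.322 with an estimated correlation), but not without Vector replicate 3 (0.0749) or FTO replicate 3 (0.0685). The integrin beta chain ITGB3 fell 2.44-fold and 27 members did not pass (2 fell and 1 rose adjusted over the list alone). ITGB3 kept its call only without Vector replicate 1 or 3 (edgeR adjusted p = 0.0784 to 0.253 in the others). Genes of EGFR ligands and receptors, which drive keratinocyte growth, had a median of −0.25, and −0.13 without Vector replicate 3 (camera adjusted p = 0.0472; adjusted p = 0.2995 with an estimated correlation). That call was lost without Vector replicate 1 (0.0601) or 3 (0.227), FTO replicate 1 (0.0688) or 3 (0.0525), or mut-FTO replicate 3 (0.0502). No EGFR list member passed by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, against 1 higher and 2 lower of 12 at an unadjusted p below 0.05. Without Vector replicate 3 more members passed: 15 interferon-response genes fell, matrix genes fell in 16 and rose in 5 cases, cytokine genes fell in 5 and rose in 2, and glycolysis genes rose in 4 and fell in 2. Integrin genes then fell in 3 cases and rose in 1, and 1 EGFR list member rose.

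The mutant enzyme was set against Vector to ask what expression of FTO with disrupted demethylase activity does to these cells. In mut-FTO differentiation genes were higher and interferon-response genes lower than in Vector. Of 28 cytokine genes 11 fell and 4 rose. Matrix genes and EGFR ligands and receptors fell as lists at the preset correlation, calls that were lost with an estimated one (adjusted p = 0.102 and 0.171). SPINK6, an inhibitor of the kallikrein proteases of the skin surface, was not counted in Vector and reached 7.07 ± 0.594 CPM, at least 237-fold higher. IL33, an alarmin cytokine of epithelial cells, stood at 2.58 ± 1.94 CPM in Vector and was not counted in mut-FTO, at least 91.9-fold lower by total counts. KRT1 rose 24.9-fold to 90.3 ± 4.01 CPM, and IFI6 fell 86.9-fold to 2.46 ± 0.378 CPM. FAM3D was likewise not counted in Vector and was at least 55.6-fold higher in mut-FTO. The growth factor binding protein IGFBP2 rose 82.0-fold, the lipid transporter ABCA4 87.6-fold, the small matrix proteoglycan decorin (DCN) 52.2-fold, TMEM37 39.7-fold, the chemokine CXCL14 32.6-fold and LRRC32, which tethers latent TGF-beta, 29.6-fold. These folds rest on few Vector counts, in total 8 for IGFBP2, 7 for ABCA4, 4 for DCN, 27 for TMEM37, 23 for CXCL14 and 10 for LRRC32. By total counts the potassium channel KCNK3 was at least 76.5-fold lower, coagulation factor F5 at least 63.1-fold and SH2D2A at least 44.6-fold. The growth factor FGF5 was at least 42.6-fold and the receptor kinase ROR2 at least 39.3-fold lower, and none of these genes was counted in mut-FTO. The transcription factor FLI1 fell 150-fold by its total counts without TMM factors (counting interval 41.2 to 1244) and 119.9-fold by edgeR. For genes without a count, the 3 libraries together were set at 3 counts. These bounds use library totals without TMM factors, which were 1.012 to 1.052 in Vector and 0.9143 to 1.017 in mut-FTO. With those factors the bounds on genes absent from mut-FTO would be lower.

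In total 449 genes rose and 618 fell of 13713 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 2899 had an unadjusted p below 0.05. Of these 1067 genes, 1063 separated every mut-FTO library from every Vector library, as did 24.0% of all tested genes, where chance gives 10%. DESeq2 called 1680 genes, a fit of the 6 samples compared 621, the fit without Vector replicate 3 and mut-FTO replicate 2 called 2401, and a lower limit of 2-fold on the change left 702. Leaving out 1 library gave 2089 genes without Vector replicate 3, 651 without mut-FTO replicate 2 and 609 without mut-FTO replicate 3. Of the 16 genes of largest change, ROR2 lost its call without any of the mut-FTO libraries (edgeR adjusted p = 0.0606 to 0.0690), and the other 15 kept theirs with any of the 9 libraries left out.

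Keratinocyte differentiation genes rose together in mut-FTO: 17 of 34 tested members rose and 17 did not pass (22 rose adjusted over the list alone). The median log2 fold change was 1.17 (camera adjusted p = 4.37e-17; adjusted p = 0.00566 with an estimated correlation). SPRR2E rose 12.6-fold to 87.8 ± 5.02 CPM, SPRR2D 6.54-fold and SPRR2A 6.29-fold. Genes raised in psoriasis lesions rose as a list (median 0.30; camera adjusted p = 0.00245; adjusted p = 0.116 with an estimated correlation). Among 30 tested members 5 rose and 25 did not pass (9 rose and 3 fell adjusted over the list alone). They included AKR1B10, an aldo-keto reductase, 10.2-fold higher, PI3 (elafin), an elastase inhibitor, 3.96-fold higher at 1496 ± 427 CPM, and KRT16, a keratin of stressed and hyperproliferative epidermis, 4.01-fold higher. Interferon-response genes fell: 20 of 42 members fell and 22 did not pass (27 fell adjusted over the list alone), with a median of −0.88 (camera adjusted p = 5.21e-17; adjusted p = 0.00130 with an estimated correlation). IFIT2, whose product binds foreign RNA, fell 5.70-fold to 7.66 ± 1.32 CPM, OAS2 5.38-fold and MX1 4.81-fold. IFIT genes form a family that can share reads. Cytokine genes went both ways, 11 of 28 falling, 4 rising and 13 not passing (13 fell and 4 rose adjusted over the list alone), with a median of −0.44 (camera adjusted p = 6.78e-05; adjusted p = 0.0402 with an estimated correlation). That last call was lost with any library but mut-FTO replicate 3 left out (adjusted p = 0.0541 to 0.0966 with an estimated correlation), and the median was −0.28 without mut-FTO replicate 1. IL1B fell 8.73-fold from 409 ± 33.5 to 46.9 ± 4.58 CPM, IL24 12.8-fold, IL1A (interleukin 1 alpha) 8.31-fold and the chemokine CCL5 4.59-fold. Leukocyte markers fell as a list (median −0.76; camera adjusted p = 0.0220, and 0.1003 without mut-FTO replicate 1; adjusted p = 0.236 with an estimated correlation). LCP1 fell 9.28-fold, CD74 3.68-fold and HLA-DRA 3.16-fold, CD14, a co-receptor for lipopolysaccharide, rose 2.01-fold, and 3 of 7 did not pass (3 fell and 2 rose adjusted over the list alone). The leukocyte median was −0.33 without Vector replicate 3, −0.16 without mut-FTO replicate 1 and −1.71 without mut-FTO replicate 2.

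Matrix genes fell in mut-FTO, 16 of 45 falling, 3 rising and 26 not passing (21 fell and 4 rose adjusted over the list alone), with a median of −0.53 (camera adjusted p = 7.59e-10; adjusted p = 0.102 with an estimated correlation). THBS1 (thrombospondin 1) fell 3.29-fold to 60.2 ± 10.4 CPM and the metalloproteinase inhibitor TIMP2 6.23-fold. Integrin and focal adhesion genes fell as a list (median −0.15; camera adjusted p = 0.0147, and 0.0982 without mut-FTO replicate 1; adjusted p = 0.294 with an estimated correlation). Of 28 members 3 fell, 2 rose and 23 did not pass (4 fell and 2 rose adjusted over the list alone), and the median was −0.24 without Vector replicate 1 and −0.25 without mut-FTO replicate 2. ITGB3 fell 6.93-fold and ITGA5, the alpha chain of the fibronectin receptor, 2.56-fold. TGF-beta targets and epithelial-mesenchymal transition genes, a list that also holds FN1, had a median of −0.53 (camera adjusted p = 0.0154; adjusted p = 0.171 with an estimated correlation). In this list 5 of 23 fell, 3 rose and 15 did not pass (7 fell and 3 rose adjusted over the list alone), and without Vector replicate 3 the list missed the threshold (0.0526; median −0.22). The median was −0.35 without mut-FTO replicate 1. Genes of EGFR ligands and receptors fell (median −0.62; camera adjusted p = 0.0135, and 0.0502 without Vector replicate 3; adjusted p = 0.171 with an estimated correlation). The ligands NRG1 (2.16-fold), HBEGF (2.12-fold) and TGFA (1.73-fold) fell, while 9 of 12 members did not pass (6 fell adjusted over the list alone). Immediate early and AP-1 genes fell, 8 of 30 falling, 1 rising and 21 not passing (9 fell and 1 rose adjusted over the list alone), with a median of −0.43 (camera adjusted p = 3.88e-05; adjusted p = 0.166 with an estimated correlation). The MAP kinase phosphatases DUSP6, DUSP4 and DUSP5 fell 2.13-fold, 2.62-fold and 3.04-fold.

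Cell cycle genes fell as a list in mut-FTO (median −0.38; camera adjusted p = 2.53e-05; adjusted p = 0.0130 with an estimated correlation, and 0.0508 with that correlation without Vector replicate 1). RRM2, a subunit of ribonucleotide reductase, fell 2.19-fold to 9.96 ± 1.13 CPM, and 9 of 49 members fell, 1 rose and 39 did not pass (14 fell and 1 rose adjusted over the list alone). Of p53 targets 3 of 24 fell and 21 did not pass (5 fell adjusted over the list alone), among them the cytokine GDF15 (13.9-fold) and the apoptosis gene PMAIP1 (2.17-fold). Their median was −0.20 (camera adjusted p = 0.0183; adjusted p = 0.274 with an estimated correlation), and the call was lost without Vector replicate 1 (0.0910) or 2 (0.0724) or mut-FTO replicate 2 (0.0955). The p53 median was −0.13 without Vector replicate 2, −0.36 without Vector replicate 3 and −0.36 without mut-FTO replicate 1. Stress-response genes of unfolded proteins fell as a list (median −0.24; camera adjusted p = 0.0183; adjusted p = 0.390 with an estimated correlation), but not without Vector replicate 1 (0.129) or 2 (0.104). Among them 4 of 40 fell and 36 did not pass (8 fell and 3 rose adjusted over the list alone), including the transcription factors ATF3 (3.61-fold) and DDIT3 (1.78-fold). ATF3 lost its call without Vector replicate 2 or any mut-FTO library (edgeR adjusted p = 0.0539 to 0.0989). DDIT3 lost it without Vector replicate 1 or 2 or any mut-FTO library (0.0539 to 0.103). Ribosomal protein genes rose as a list, with a median of 0.61 (camera adjusted p = 7.44e-20; adjusted p = 0.234 with an estimated correlation) that was 0.44 without Vector replicate 3. Of 75 members 6 rose, such as RPL27A (1.86-fold), and 69 did not pass (48 rose adjusted over the list alone). Nuclear oxidative phosphorylation genes rose as a list, with a median of 0.56 (camera adjusted p = 1.43e-11; adjusted p = 0.275 with an estimated correlation) that was 0.33 without Vector replicate 3. Of 49 members 4 rose, such as the ATP synthase gene ATP5O (1.68-fold), and 45 did not pass (11 rose adjusted over the list alone). RPL27A lost its call without Vector replicate 2 or mut-FTO replicate 1 or 2 (edgeR adjusted p = 0.0658 to 0.120), and ATP5O without Vector replicate 2 (0.0508). Mitochondrially encoded genes had a median of −0.22 and missed the threshold (camera adjusted p = 0.936), but without Vector replicate 3 they rose, with a median of 0.72 (camera adjusted p = 1.04e-09; adjusted p = 0.221 with an estimated correlation). Without Vector replicate 3 more members of these lists passed. Then 25 ribosomal protein, 14 oxidative phosphorylation and 11 mitochondrially encoded genes rose, while cell cycle genes fell in 19 cases and rose in 1, p53 targets in 11 and 1, integrin genes in 7 and 2, and unfolded protein response genes in 14 and 3.

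FTO was compared with mut-FTO to ask what depends on the enzyme's demethylase activity, at FTO RNA levels that did not differ by more than the spread between libraries. Differentiation genes were lower, and interferon-response genes higher, in FTO than in mut-FTO, and 5 of 28 cytokine genes were higher. KRT1 stood at 22.4 ± 2.34 CPM in FTO against 90.3 ± 4.01 in mut-FTO, and IL1B at 216 ± 23.0 against 46.9 ± 4.58 CPM. RNASE2 was 124-fold higher in FTO, CPPED1, a phosphatase, 31.4-fold, and CFI, a protease that inactivates complement C3b, 11.1-fold. IFI6 was 8.75-fold and SLFN11, an interferon-inducible helicase-like protein, 8.59-fold higher. SPINK6 was 15.1-fold lower in FTO, TMEM37 9.51-fold and ABCA4 7.69-fold. These changes passed edgeR's threshold with any of the 9 libraries left out. In mut-FTO RNASE2 and CPPED1 had 8 counts each in total and CFI 17, so their folds rest on few counts. The peroxidase PXDN (12.1-fold), FOLR3 (10.8-fold) and the interferon-induced IFI44 (8.79-fold) were also higher in FTO. TSPAN7 (12.5-fold), IGFBP2 (11.01-fold), CXCL14 (9.87-fold), the homeobox gene EN1 (9.21-fold) and the sterol transporter ABCG1 (7.53-fold) were lower. Total counts in mut-FTO were 27 for PXDN, 14 for FOLR3 and 20 for IFI44. Those in FTO were 12 for TSPAN7, 65 for IGFBP2, 80 for CXCL14, 26 for EN1 and 35 for ABCG1.

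In total 164 genes were higher and 155 lower in FTO than in mut-FTO of 13713 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 1918 had an unadjusted p below 0.05. All 319 separated every library of the 2 groups, as did 29.02% of all tested genes, where chance gives 10%. DESeq2 called 751 genes, a fit of the 6 samples compared 1218, and the fit without Vector replicate 3 and mut-FTO replicate 2 called 1196. The fit that called 319 shares its estimate of the spread with Vector, the group of largest spread, although Vector is not compared here. Leaving out 1 library gave 1427 genes without Vector replicate 3, 106, 74 and 71 without FTO replicates 1, 2 and 3, and 102 and 105 without mut-FTO replicates 2 and 3. Calls by edgeR were lost for PXDN without any FTO library or mut-FTO replicate 3 (adjusted p = 0.0596 to 0.106), and for FOLR3 without any FTO library or mut-FTO replicate 2 (0.0661 to 0.125). IFI44 lost its call without any FTO library, Vector replicate 2 or mut-FTO replicate 3 (0.0540 to 0.159), and IGFBP2 without FTO replicate 2 or 3 (0.0570 to 0.0574). TSPAN7 and ABCG1 lost it without any FTO or mut-FTO library (0.0709 to 0.136 and 0.0537 to 0.166). CXCL14 lost it without any FTO library or mut-FTO replicate 2 or 3 (0.0629 to 0.0950), and EN1 without FTO replicate 2 or 3 or mut-FTO replicate 2 (0.0574 to 0.0714). Exchanging the names of the 2 groups would turn the sign of every difference here. Their comparisons with Vector would then trade places as well.

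Differentiation genes were lower in FTO than in mut-FTO, with 10 of 34 members lower and 24 not passing (20 lower adjusted over the list alone), SPRR2E among them at 23.1 ± 2.42 against 87.8 ± 5.02 CPM. Their median log2 difference was −1.05 (camera adjusted p = 6.52e-18; adjusted p = 0.0105 with an estimated correlation). Psoriasis lesion genes were lower as a list (median −0.19; camera adjusted p = 0.00457; adjusted p = 0.167 with an estimated correlation). AKR1B10 was 3.11-fold and PI3 2.45-fold lower, and 3 of 30 members were lower and 27 did not pass (4 lower adjusted over the list alone). The median was −0.13 without FTO replicate 1. AKR1B10 lost its call without FTO replicate 1 or 2 or mut-FTO replicate 2 or 3 (edgeR adjusted p = 0.0673 to 0.0870), and PI3 without any FTO library or mut-FTO replicate 2 (0.0562 to 0.0936). Interferon-response genes were higher, 8 of 42 passing and 34 not (11 higher adjusted over the list alone), with a median of 0.37 (camera adjusted p = 6.67e-06; adjusted p = 0.0141 with an estimated correlation, and 0.0726 with that correlation without mut-FTO replicate 1). IFIT2 stood at 28.5 ± 0.712 CPM in FTO against 7.66 ± 1.32 in mut-FTO. Cytokine genes were higher, 5 of 28 passing and 23 not (10 higher and 2 lower adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.000159; adjusted p = 0.0484 with an estimated correlation). That last call was lost without any Vector or FTO library or mut-FTO replicate 1 (adjusted p = 0.0553 to 0.0929 with an estimated correlation). IL24 was 5.14-fold higher in FTO.

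Matrix genes were called higher in FTO than in mut-FTO (camera adjusted p = 0.00869, and 0.143 without mut-FTO replicate 1; adjusted p = 0.374 with an estimated correlation), although their median was −0.030 and their mean 0.22. The median turned to 0.013 when libraries were scaled by their size alone and ranged from −0.049 to 0.12 with 1 library left out, being lowest without FTO replicate 1 and highest without mut-FTO replicate 3. It was 0.0011 without Vector replicate 2, 0.043 and 0.014 without FTO replicates 2 and 3, and 0.011 without mut-FTO replicate 2. In this list 8 of 45 were higher, THBS1 by 3.59-fold, and 37 did not pass (11 higher and 2 lower adjusted over the list alone). Immediate early genes were higher, 4 of 30 passing and 26 not (8 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000147; adjusted p = 0.188 with an estimated correlation). DUSP5 was 3.42-fold higher with any library left out, and DUSP4 2.44-fold, a call lost without FTO replicate 2 or 3 or mut-FTO replicate 3 (edgeR adjusted p = 0.0524 to 0.0590). Of p53 targets, PMAIP1 was 2.08-fold higher and 23 of 24 did not pass (3 higher adjusted over the list alone), with a median of 0.27, and 0.16 without mut-FTO replicate 2 (camera adjusted p = 0.00189; adjusted p = 0.188 with an estimated correlation). PMAIP1 lost its call without FTO replicate 2 or 3 or mut-FTO replicate 2 or 3 (edgeR adjusted p = 0.0780 to 0.0932). The glucose transporter SLC2A3 was 2.78-fold higher in FTO, while 34 of 35 glycolysis and hypoxia genes did not pass (3 higher adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.000866; adjusted p = 0.374 with an estimated correlation). Unfolded protein response genes had a median of 0.28 (camera adjusted p = 6.67e-06; adjusted p = 0.167 with an estimated correlation), against the direction of their 1 member past the threshold, the transcription factor ATF5, 1.67-fold lower. The other 39 did not pass (9 higher and 1 lower adjusted over the list alone), and ATF5 lost its call without any FTO library or mut-FTO replicate 2 or 3 (edgeR adjusted p = 0.0939 to 0.15). Cell cycle genes had a median of 0.23 (camera adjusted p = 0.000365; adjusted p = 0.0277 with an estimated correlation, and 0.0618 and 0.0907 with that correlation without FTO replicate 1 and mut-FTO replicate 1). No cell cycle gene of 49 passed by edgeR or limma-voom, or adjusted over the list alone, against 4 by DESeq2 and 9 at an unadjusted p below 0.05. Mitochondrially encoded genes were called lower in FTO only as a list, at the preset correlation (median −0.71; camera adjusted p = 0.000273; adjusted p = 0.487 with an estimated correlation). None of these 13 passed by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, against 1 at an unadjusted p below 0.05. Without Vector replicate 3 all 13 were lower by edgeR (camera adjusted p = 4.60e-13; adjusted p = 0.195 with an estimated correlation). Other lists also gained members then: 19 differentiation and 7 psoriasis lesion genes were lower, and 15 interferon-response, 11 immediate early, 4 p53 target and 4 cell cycle genes higher. Cytokine genes were higher in 8 cases and lower in 2, matrix genes in 13 and 5, glycolysis genes in 7 and 1, and unfolded protein response genes in 12 and 2.

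Genes changed by FTO in comparison with both Vector and mut-FTO numbered 5, and 38 further genes passed both tests in opposite directions. RNASE2 and GPC4 were higher in FTO than in either other group, with RNASE2 at 10.1 CPM in FTO, 0 in Vector and 0.0721 in mut-FTO and GPC4 at 7.13, 0.988 and 2.38 CPM. MYO1G and DAGLA, a lipase that makes an endocannabinoid, were lower, with DAGLA at 0.922 CPM against 2.94 in Vector and 2.502 in mut-FTO. Both lay near the threshold against Vector and mut-FTO, DAGLA at edgeR adjusted p = 0.04745 and 0.04945 and MYO1G at 0.03638 and 0.03865. The fifth, an assembled locus without a gene name, was higher in FTO and was picked out after its values were seen. Independent lists would share 0.502 higher and 0.678 lower genes, and 20 simulations of unchanged groups sharing the FTO libraries gave 0.1 genes on average and at most 1. No simulated gene was changed, so few can pass, and the part that shared FTO libraries have in the real count is not shown. The count of 5 was 17 with DESeq2, 3 in fits of the 6 samples compared, 3 without assembled loci and mitochondrial genes, and 55 without Vector replicate 3 and mut-FTO replicate 2. Leaving out 1 library gave 3, 2 and 1 without FTO replicates 1, 2 and 3, 3 without Vector replicate 2, 47 without Vector replicate 3, and 2 and 3 without mut-FTO replicates 2 and 3.

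Far more genes moved the same way in both expressing groups. Against Vector, 38 genes rose and 55 fell in FTO and in mut-FTO alike by the edgeR test. KRT1, SPINK6, DCN, LSP1 and ABCA4 led the genes raised in both groups, and IFI27, BST2, IFI6, FN1 and NFATC1 those lowered in both. DCN was at 0.0373 CPM in Vector, 0.784 in FTO and 2.15 in mut-FTO, and IFI27 at 74.4, 6.25 and 3.42 CPM. The call of DCN in FTO against Vector was kept only without Vector replicate 2 or 3 (edgeR adjusted p = 0.0879 to 0.233 with any other library left out). All 102 genes changed by FTO had a log2 fold change of the same sign in mut-FTO. In the simulated unchanged groups against the same Vector libraries, 93.3% of the 102 genes of lowest p did so on average (89.2% to 99.0%). The change was larger in mut-FTO for 75 of the 102. A difference between the groups was itself called for 43 of the 102, with mut-FTO further from Vector in 38 and FTO in 5. Independent lists would share 1.38 raised and 2.70 lowered genes, and 20 simulations of unchanged groups against the same Vector libraries shared 0. Since no simulated gene was changed, few can pass in either comparison. Those simulations therefore do not show how many of the 93 shared calls come from the shared Vector libraries. The count of 93 was 292 with DESeq2, 33 in fits of the 6 samples compared and 729 without Vector replicate 3 and mut-FTO replicate 2. Leaving out 1 library gave 30, 30 and 26 without FTO replicates 1, 2 and 3, 43 without Vector replicate 2, 365 without Vector replicate 3 and 52 without mut-FTO replicate 3.

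Over all 13713 genes the log2 fold changes of FTO and mut-FTO against Vector had a covariance of 0.271 and a correlation of 0.584 across genes, which are not independent replicates, and 71.5% had the same sign. Simulated unchanged groups against the same Vector libraries gave a covariance of 0.0748 ± 0.00672 (SD of 20 runs), a correlation of 0.503 and 66.8% of the same sign. In these simulations all groups had the same spread, whereas the measured spread was largest in Vector. The measured variance of the mean of the 3 Vector libraries, averaged over genes on log2 CPM, was 0.104. Shared controls alone would add about that much to a covariance on log2 CPM, while the simulated 0.0748 and the measured 0.271 are on edgeR fold changes. With FTO and mut-FTO set against different single Vector libraries, the covariance on log2 CPM was 0.125 on average over 6 choices (0.0578 to 0.165; jackknife SE over the Vector libraries 0.0652). Over the 3 choices that shared a library it was 0.437. Neither value is on the scale of the 0.271. On edgeR fold changes the covariance was 0.483 without Vector replicate 1 and 0.410 without Vector replicate 2. Choices of different libraries carry no noise of a shared library, but their mean lay within 2 jackknife SE of 0. Since 3 Vector libraries cannot be split into parts of at least 2 each, part of the excess of 0.271 over its simulated value may come from the shared controls.

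Some lists passed in another comparison but missed the threshold in FTO against Vector (camera adjusted p). These were psoriasis lesion genes (0.0856), TGF-beta targets (0.132), cell cycle genes (0.0793), p53 targets (0.959), immediate early genes (0.258) and unfolded protein response genes (0.0916). In mut-FTO against Vector glycolysis and hypoxia genes missed it (0.409). In FTO against mut-FTO it was missed by integrin genes (0.297), TGF-beta targets (0.0580), EGFR ligands and receptors (0.134), ribosomal protein genes (0.587), nuclear oxidative phosphorylation genes (0.108) and leukocyte markers (0.735).

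The remaining lists did not pass in any comparison, given here as camera adjusted p for FTO against Vector, mut-FTO against Vector and FTO against mut-FTO in turn. Genes that write, erase and read methylated adenosine, FTO left out, gave 0.931, 0.936 and 0.778. No member of that list passed by edgeR, DESeq2 or limma-voom in any comparison, against 2, 1 and 0 of 25 at an unadjusted p below 0.05. Basal keratinocyte and hemidesmosome genes gave 0.0668, 0.109 and 0.745, with members moving both ways in mut-FTO against Vector. There the laminin chain LAMA3, part of the epidermal basement membrane, fell 2.52-fold, and the basal keratin KRT15 rose 2.48-fold to 2064 ± 290 CPM, each with any of the 9 libraries left out. NF-kB targets gave 0.964, 0.228 and 0.0944, although TNFAIP2, induced by tumor necrosis factor, rose 2.79-fold in mut-FTO against Vector. Wnt, Hippo and Notch targets gave 0.922, 0.798 and 0.778, and CCND1 (cyclin D1) fell 2.12-fold in mut-FTO against Vector. Cholesterol and lipid synthesis genes gave 0.350, 0.936 and 0.652, NRF2 targets and metallothioneins 0.0856, 0.282 and 0.778, and heat shock genes 0.526, 0.936 and 0.652. Replication-dependent histone genes, whose RNA has no poly(A) tail, gave 0.0668, 0.936 and 0.0671, and as near-identical copies they can share reads. Fibroblast markers gave 0.959, 0.936 and 0.595, with 8 of 14 genes tested and DCN past the threshold in both expressing groups against Vector. Melanocyte and endothelial markers were too few to test, with PMEL and MITF at most at 1.37 CPM and CDH5 at 1.11 CPM. Among lists past the preset-correlation test, median, mean and test differed in sign only for matrix genes in FTO against mut-FTO. Among the others they differed for NF-kB, TGF-beta, p53 and Wnt lists in FTO against Vector. They also differed for methylated-adenosine, heat shock, mitochondrial, histone and fibroblast lists in mut-FTO against Vector and for methylated-adenosine, Wnt and leukocyte lists in FTO against mut-FTO. With the preset correlation 11, 15 and 11 of 26 lists passed, and with an estimated correlation 1, 4 and 4.

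**Figure D3:**
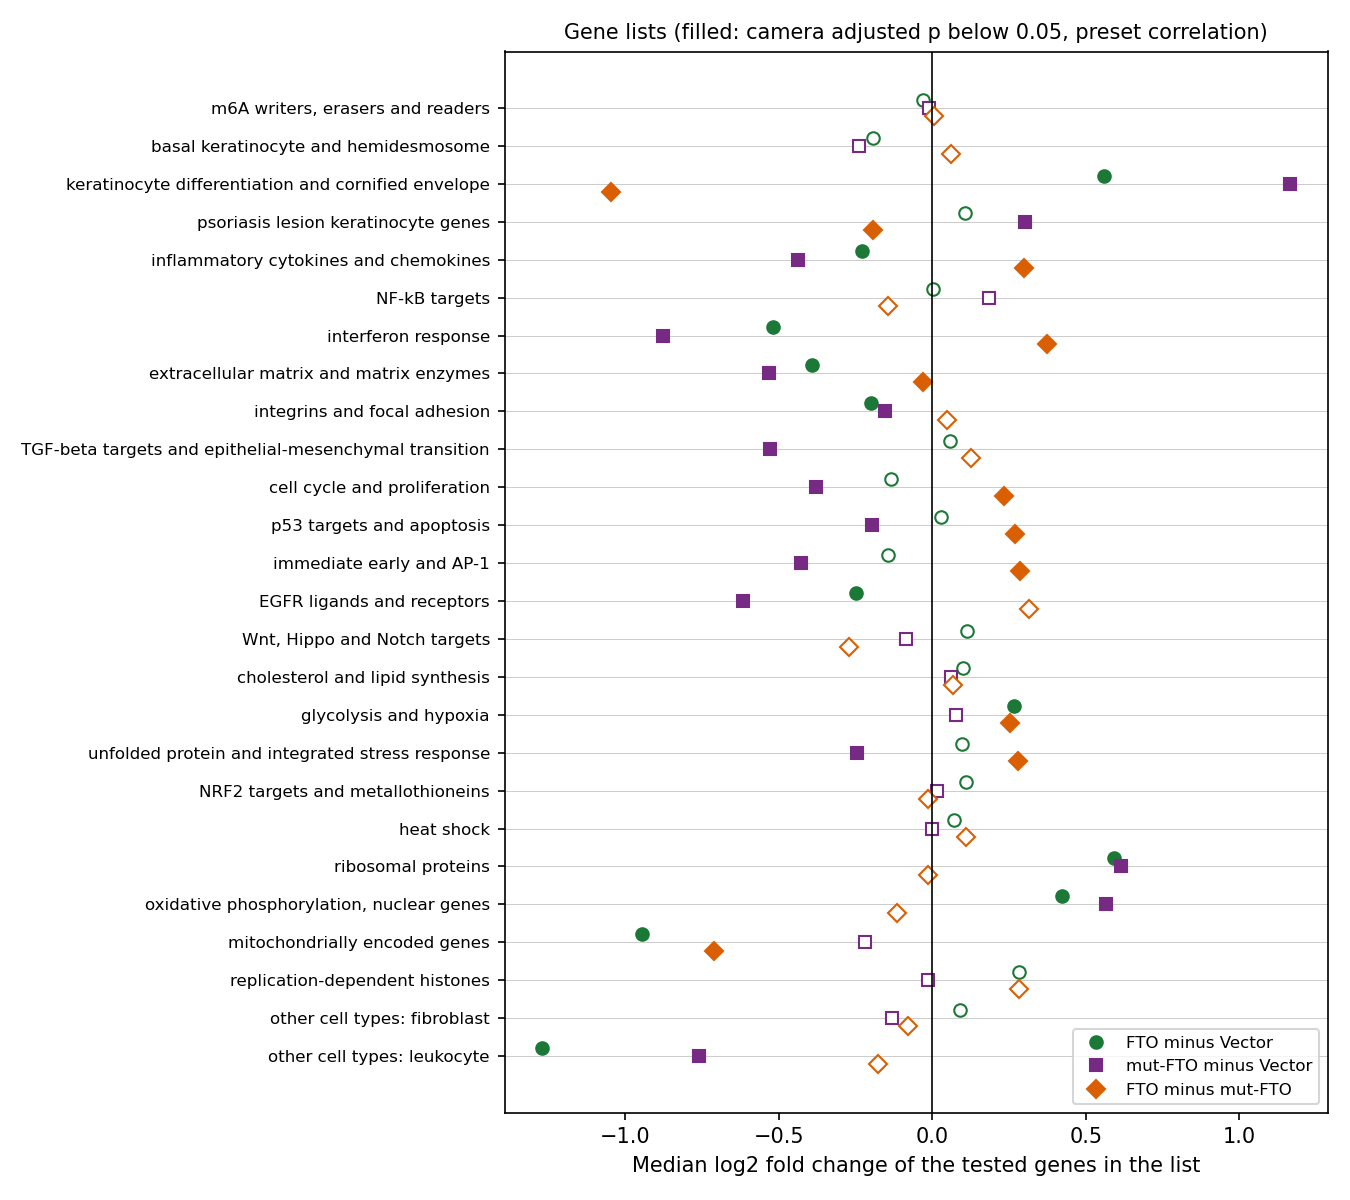
Median log2 fold change (x axis) of the tested members of 26 gene lists (y axis) for FTO minus Vector (circles), mut-FTO minus Vector (squares) and FTO minus mut-FTO (diamonds), filled where the camera adjusted p at the preset correlation was below 0.05. Differentiation genes lay at 0.56 and 1.17 against Vector and interferon-response genes at −0.52 and −0.88, while mitochondrially encoded genes lay at −0.95, −0.22 and −0.71.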

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

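Tests chosen after their result was seen were that of FN1 in Vector replicate 3 for a wrong label those of the ribosomal and oxidative phosphorylation lists without Vector replicate 3, the jackknife error of the covariance, and the counts among regroupings that kept a group whole.

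FTO and mut-FTO differed from each other by the direct edgeR test. The number of genes that differed was 319. Against Vector, FTO lay between Vector and mut-FTO in 219 of them, beyond mut-FTO on the same side in 6 and on the opposite side in 93, and CLEC10A, the remaining 1, was counted in FTO alone. These sides are signs of fold changes: 282 of the 319 were called in mut-FTO against Vector and 43 in FTO against Vector. All 102 genes called in FTO against Vector had the same sign in mut-FTO, so none of the 93 was called in FTO. Higher in FTO were RNASE2 (log2 difference 6.96), CPPED1 (4.97), PXDN (3.596), CFI (3.47), FOLR3 (3.44), IFI44 (3.14), IFI6 (3.13), SLFN11 (3.10) and FN1 (1.98). Lower in FTO were SPINK6 (−3.92), TSPAN7 (−3.65), IGFBP2 (−3.46), CXCL14 (−3.30), TMEM37 (−3.25), EN1 (−3.20), ABCA4 (−2.94) and ABCG1 (−2.91).

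Gene lists differed between FTO and mut-FTO too, by camera adjusted p at the preset correlation. Lower in FTO were keratinocyte differentiation genes (6.52e-18), with KRT1 at a log2 difference of −2.01 and SPRR2E at −1.93, and psoriasis lesion genes (0.00457), with AKR1B10 at −1.64 and PI3 at −1.29. Higher in FTO were cytokine genes (0.000159; IL1B 2.21, IL24 2.36), interferon-response genes (6.67e-06; IFIT2 1.89) and matrix genes (0.00869; THBS1 1.84). Immediate early genes (0.000147; DUSP5 1.77, DUSP4 1.29), p53 targets (0.00189; PMAIP1 1.06) and glycolysis and hypoxia genes (0.000866; SLC2A3 1.48) were higher as well. Cell cycle genes (0.000365) were higher without a member past the threshold by edgeR, against 9 at an unadjusted p below 0.05 and 4 by DESeq2. Unfolded protein response genes were higher as a list (6.67e-06) while ATF5 was lower (−0.74), and mitochondrially encoded genes were lower as a list (0.000273) with 0 of 13 members past the threshold by edgeR or DESeq2, against 1 at an unadjusted p below 0.05. With an estimated correlation the calls held for differentiation (adjusted p = 0.0105), interferon-response (0.0141), cytokine (0.0484) and cell cycle genes (0.0277). They were lost for psoriasis lesion (adjusted p = 0.167), matrix (0.374), immediate early (0.188), p53 (0.188), glycolysis (0.374), unfolded protein response (0.167) and mitochondrial genes (0.487). With that correlation and each of the 9 libraries left out in turn, the cytokine call was lost in 7 cases (adjusted p up to 0.0929), the cell cycle call in 2 (up to 0.0907) and the interferon call in 1 (0.0726). The matrix median was −0.030, against the list's direction, and its call at the preset correlation was lost without mut-FTO replicate 1 (0.143).

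Calls lost with a library left out are given in the report beside genes named by their largest change or as list members. They are not given for genes named by an overlap alone, such as DAGLA, nor for MYO1G and GPC4 against mut-FTO. With 3 libraries per group only 10 splits of 6 libraries exist, too few for a share under 0.05. The real split of FTO and mut-FTO gave 319 genes and the highest other 1, so that 1 split reached the real count. The other splits mix the groups, so a difference between them adds to the spread and few genes can pass. For lists the real split gave 11 and the highest other 16, with 3 splits at or above 11.

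Vector replicate 3 lay farther from the other Vector libraries than they lay from each other, with a distance ratio of 1.57 against at most 1.11 in FTO and mut-FTO. Without mitochondrial genes and assembled loci the ratio was 1.60, above the 1.5 set beforehand, so the distance lay in the other genes too. The distance weighs every gene alike on libraries scaled by TMM factors, so leaving out a few rows could hardly lower it. Whether counts taken by a few transcripts are the cause is therefore not decided by that test. A mislabelled FTO or mut-FTO library is argued against by the FN1 level of Vector replicate 3, 279 CPM. That is above every FTO and mut-FTO library and near the 220 and 230 CPM of the other Vector libraries. Length and GC content stay open: their trend held 38.1% of its deviation, and removing it took the ratio from 1.66 on the matched genes to 1.39, between the limits set beforehand and above the at most 1.11 of FTO and mut-FTO libraries. No biological explanation was tested, since the labels tell the Vector libraries apart by number alone.

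The changes of FTO and mut-FTO against Vector went the same way, with a covariance of 0.271 over all genes. How much of it comes from sharing the Vector libraries cannot be told apart from a shared effect with 3 Vector libraries. With different Vector libraries the covariance was 0.125 on average (0.0578 to 0.165), on log2 CPM where the 0.271 is on edgeR fold changes. It was above 0 in each of 6 choices but within 2 jackknife SE (0.0652) of 0. It was also below the level set beforehand relative to the 0.437 of choices that share a library. Regrouping the 9 libraries 100 times gave 7 covariances as large, the real one included, the highest other 0.424, so chance was not excluded by that count. All 7 were among the 9 that kept a group whole in the place of Vector and so carry that group's own difference, while of the 91 that mixed groups there 0 were as large, the highest 0.198.

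Ribosomal protein and nuclear oxidative phosphorylation genes were called higher as lists in mut-FTO against Vector at the preset correlation, with medians of 0.61 and 0.56, but not with an estimated one (adjusted p = 0.234 and 0.275), and 6 of 75 and 4 of 49 members rose. Vector replicate 3 as the whole cause is argued against, since without it the medians were 0.44 and 0.33 and both lists passed camera. A trend in length and GC content as the whole cause is argued against by medians of 0.56 (bootstrap interval 0.508 to 0.593) and 0.45 (0.298 to 0.571) after its removal. These intervals resample the genes of a list as if they were independent and leave out the spread between libraries. Variation shared among the genes of a list, which the estimated correlation allows for, and an effect of mut-FTO both stay open.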

How the results depend on the processing

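Chosen after the data were seen were the fits without Vector replicate 3 and mut-FTO replicate 2, those without assembled loci and mitochondrial genes, those that left out a library of the group not compared, and the estimated correlation with 1 library left out.

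Counts of changed genes moved with the tool and the libraries. DESeq2 called 366 genes in FTO against Vector, 1680 in mut-FTO against Vector and 751 in FTO against mut-FTO, and held 102, 1066 and 319 of the edgeR calls. It also made 21.1%, 21.1% and 19.1% false calls in simulated counts. Fits of only the 6 samples compared called 41, 621 and 1218, holding 40, 614 and 314 of the calls. Without Vector replicate 3 and mut-FTO replicate 2 the counts were 1050, 2401 and 1196, holding 101, 981 and 317. A log2 fold change of at least 1 left 702 in mut-FTO against Vector by construction. Leaving out 1 library gave 27 to 476, 609 to 2089 and 71 to 1427 genes. The highest count in each came without Vector replicate 3, where the biological coefficient of variation was 0.174 in place of 0.244.

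The overlap of FTO against both others (5) was 17 with DESeq2, 3 with 6 samples, 3 without assembled loci and mitochondrial genes, 55 without the 2 libraries, and 1 to 47 with 1 library left out. Genes shared by FTO and mut-FTO against Vector (93) were 292 with DESeq2, 33 with 6 samples, 729 without the 2 libraries and 26 to 365 with 1 library left out. The covariance (0.271) was 0.395 without the 2 libraries and 0.29 to 0.483 with 1 left out. The log2 difference of FTO between FTO and mut-FTO, which missed the threshold, ran from −0.0726 without mut-FTO replicate 1 to 0.286 with 1 library left out. The causes of these moves were not tested. All 3 groups shared 1 estimate of the spread, and the median standard deviation of a gene was 0.37 in Vector, 0.14 in FTO and 0.23 in mut-FTO. Calls in FTO against mut-FTO therefore also rest on the spread of Vector libraries, which that comparison does not use.

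Replicate numbers did not pair the samples: same-numbered libraries had correlations of −0.127 to 0.106, 1 of 9 over 0.1. The highest correlation of 2 of the 9 libraries, Vector replicate 1 and FTO replicate 1, was with their own number, and 0 libraries correlated best with it in both other groups. With the replicate block 67 genes changed in FTO against Vector and 60 were shared by FTO and mut-FTO. It kept 153 of 175 calls of named genes and all 37 list calls, and moved no other count of changed genes or lists by over 1.5 times.

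List calls were 1, 4 and 4 with an estimated correlation, in place of 11, 15 and 11, and 7 with fry in FTO against Vector. RLE size factors and the filter on mean counts kept all 37 list calls. Of the 9 lists past the test with an estimated correlation, differentiation and interferon genes kept it with any library left out, except interferon genes in FTO against mut-FTO (1 of 9 lost, 0.0726). Cytokine genes lost it in 8 and 7 of 9 and cell cycle genes in 1 and 2 of 9, in mut-FTO against Vector and FTO against mut-FTO. Of 636 list results under alternatives 556 kept their call and 80 lost it, and of 3499 results of named genes 3092 kept it, 407 lost it and 0 turned direction. Named genes lost 37 calls in fits of only the 6 samples compared, 9 with library size alone and 8 with limma-voom. FN1 kept its call in all 3 comparisons under all settings run. Of 17167 features with a count 13713 had enough counts to test. In simulated counts edgeR recovered at most 5.97% of 1.5-fold changes, and whether depth or the spread between libraries limits this was not tested.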

Other observations

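The test of FTO RNA dose was chosen after its result was seen, as were the genes counted in a group and absent from another and the counts among regroupings that kept a group whole.

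Some genes had at least 10 counts in each library of a group and 0 in all 3 of another, which sets a bound on the other group of 3 counts in total. From Vector to mut-FTO 17 such genes disappeared, 14 of them named. MFAP2, a microfibril-associated protein, had 45, 26 and 29 counts in Vector and 29, 30 and 33 in FTO. FGF5, a growth factor of hair follicles, had 27, 41 and 59 in Vector and 34, 25 and 25 in FTO, and KCNK3 103, 96 and 29 in Vector and 44, 12 and 19 in FTO. CH25H, which makes an oxysterol, and ETV1, a transcription factor, were also absent from mut-FTO, at 10 to 18 and 10 to 14 counts in Vector.

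In the other direction RNASE2 had 355, 350 and 403 counts in FTO, 0 in every Vector library, and 8, 0 and 0 in mut-FTO. CLEC10A, a lectin of macrophages and dendritic cells, had 18, 20 and 31 counts in FTO and 0 in all 6 other libraries. SPINK6 had 17, 20 and 14 counts in FTO, 285, 205 and 226 in mut-FTO and 0 in Vector, and SPRR2G, a cornified envelope gene, 23, 10 and 14 in mut-FTO, 0, 0 and 5 in FTO and 0 in Vector. An assembled locus without a gene name, MSTRG.4406, stood at 2.28 CPM in FTO against 0.0188 in Vector and 0.0193 in mut-FTO.

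Assembled loci MSTRG.13709 to MSTRG.13712 together took 1.631% (Wilson 95% interval 1.626 to 1.635) of the counts of Vector replicate 3 and 2.613% (2.607 to 2.618) of mut-FTO replicate 2, against 0.200% to 0.363% in the other 7 libraries. Half-widths were at most 0.00551 points in all 9.

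More genes differed from Vector in mut-FTO than in FTO, 1067 against 102, and a candidate explanation is a larger dose of FTO RNA in mut-FTO. These counts would trade places if the columns of FTO and mut-FTO, matched by letters alone, were exchanged. The log2 difference of FTO RNA, FTO minus mut-FTO, was 0.091 with an SE of 0.21, within 2 SE of 0, so the data do not decide for or against a small difference in dose. RNA does not measure protein, and protein was not analysed here.

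Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. Every split but the real one mixes the groups, so a difference between them adds to the spread and few genes can pass. The low gene counts of the other splits therefore do not show whether chance can be excluded. For FTO against Vector the real split gave 102 genes and 11 lists, the highest other 1 gene and 10 lists, and 1 split reached each real value. For mut-FTO against Vector the real split gave 1067 genes and 15 lists, the highest other 1 gene and 11 lists, and 1 split reached each real value. Of 100 regroupings of the 9 libraries 2 gave as many as the 5 genes changed by FTO against both other groups, the real one included, and 4 as many as the 93 shared by FTO and mut-FTO against Vector. All of these kept a group whole in the place of the libraries that both comparisons use, 2 of the 2 such regroupings and 4 of the 9. Of the 98 and 91 that mixed groups there 0 did, with highest counts of 2 and 1. The counts part whole groups from mixed ones, so they do not show whether chance can be excluded. The highest other values were 20, with Vector whole in the place of FTO, and 245, with mut-FTO whole in the place of Vector. Both exceed the real counts, and the structure behind them is that of the groups themselves, since a whole group carries its own difference from the others.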
